A study of Caulobacter vibrioides NA1000 with 4 samples.

How the data were processed

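Total RNA from 2 BR-body enriched pellets and 2 whole cell lysates of Caulobacter vibrioides NA1000 strain JS299 was sequenced, per the labels' protocols, from 1 µg of RNA per library. Cells were grown overnight with 0.2% xylose, washed, and grown again with 500 µM vanillate. The genotype of the strain is not given in the sources used here, so whether a gene such as rne, or one of the xylose and vanillate list, is altered or under another promoter in it is open. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.8; the build, the counting rule and the treatment of reads that match several copies of a gene, tRNA or rRNA are not given in the sources used here. The deposited values are RPKM per feature, which the authors computed for each library separately, with no pooling of replicates. Samples were grouped by their titles, and every column of values was used.

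Each deposited RPKM value, multiplied by the feature's length, was a whole multiple of a library-specific step in 100% of values, within 0.01 reads, and the step gave the total reads per library. Length was the right minus the left coordinate, or the length the table gives for rRNA and tRNA. The smallest listed value corresponded to 51 reads in every library, so a blank is read as at most 50 reads and not as 0. Listed in all 4 libraries were 2207 features, 71 were blank in all, and the unlisted share of reads is given with the additional observations. At the filter used (mean of at least 1 RPKM), all 2207 were tested.

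Names came from a RefSeq gene table of the NA1000 assembly, and all 142 small RNA coordinates in the deposited table matched it exactly, so coordinates are given as the deposited table has them. Of 3886 protein-coding genes, 3840 lay inside exactly 1 transcription unit, 31 in none and 15 in 2. Gene symbols existed for 665 genes, in 423 units. That table has no product descriptions, so gene lists were matched on symbols only. Of 20 lists fixed before the data were examined, 5 had no match (TonB receptors, transporters, two-component signalling, mobile elements, hypothetical proteins) and are void. A further 3 had under 5 units and were not tested as lists: translation factors and aminoacyl-tRNA synthetases (1 unit, lepA, above the mRNA median; its synthetases were to be found by product text, and several fell by symbol into amino acid biosynthesis), the TCA cycle (3 units, 2 above and 1 below) and nucleotide biosynthesis (4 units, 1 above and 1 below; adjusted over the list alone, 2 and 2; median 0.0052, mean −0.012). A unit that holds genes of several lists counts in each. Of the mRNA units, 18 contain a whole small or housekeeping RNA on the same strand, whose reads are also counted in the unit.

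The comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), enriched minus lysate, with group as the sole term, an intensity trend and Benjamini-Hochberg adjustment at 0.05, two-sided. Fold changes on this scale understate the change of low features; folds in the text are ratios of mean RPKM. Classes and lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and lists also with fry. Class shares were compared by an exact two-sided permutation test, for which 2 against 2 libraries allow no p below 0.333. Correlations across units are descriptive. Python 3.11.15 with scipy 1.17.1 was used for shares, matched comparisons and permutations.

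RPKM divides by all reads, rRNA included, so a class that leaves the pellet raises all others. A fit relative to the mRNA median was therefore added after the data were examined: log2(RPKM), with no pseudocount, centred in each library on the median level of 2061 mRNA units (an alternative, also added later, centred on the median of their differences). The pseudocount was dropped after a test on simulated data for this comparison, in which 200 of 2061 units were changed. As many were raised as lowered, with the same replicate spread in both groups. With a pseudocount of 1 there were 76 false calls, 35.0% of all calls, because low units shrink. With none there were 6, or 4.29%. The real data gave more calls and a one-sided spread, so these percentages compare pseudocounts and are not error rates of the calls reported here. With none, 6% of 1.1-fold changes were recovered, 64% of 1.25-fold, 98% of 1.5-fold and 100% of 2-fold, from 50 units each. These recoveries hold for the simulated spread and number of changed units. They are not the sensitivity of the fit to the real data.

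Genes were named by a rule written beforehand: the 8 mRNA units with a symbol and the 4 noncoding RNAs that changed most in each direction among those past the threshold with no overlap between groups, up to 2 units without a symbol per direction, and rne, pnp, rhlB, rhlE, acnA, rnd and hfq. The same rule was applied to the fit relative to the mRNA median, a step added later. Members of lists and small RNAs named outside this rule were chosen after their values were seen. Replicates were checked against sampling noise: over mRNA units the chi-square per degree of freedom was 9.28 between the enriched libraries and 1.77 between the lysates, so both pairs differed by more than sampling noise.

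Alternatives were the replicate number as a block, leaving out each library, no intensity trend, centring on the mRNA median, leaving out rRNA and tRNA, no filter or a mean of at least 10 RPKM, and pseudocounts of 0.1 and 10. Added after the data were examined were blanks set to 50 reads, voom weights on recovered reads, subtraction of nested RNA reads, list tests among mRNA units and, for the fit relative to the mRNA median only, scaling to summed mRNA reads. The share of rRNA left in each pellet limits what RPKM can say of absolute amounts, which were not measured here.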

Results

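RNA was sequenced from Caulobacter vibrioides NA1000 (strain JS299), a freshwater alphaproteobacterium whose RNase E gathers with RNA in condensates called bacterial ribonucleoprotein bodies (BR-bodies). Frozen cells were milled, and a BR-body enriched pellet was collected by successive spins at 2000, 10000 and 20000 ×g. A portion of the milled lysate taken before the spins served as the whole cell lysate. Each group had 2 libraries of total RNA, and the comparison asks which RNAs were found in the pellet relative to the cell as a whole. The deposited values are RPKM, read counts scaled to feature length and library size, for 2426 features: 2238 mRNA transcription units, 131 small RNAs, 8 antisense RNAs, 3 housekeeping RNAs, 43 tRNAs and 3 rRNAs. Library sizes recovered from the values were 35603399 and 39661110 reads for the enriched fraction and 43129979 and 34361231 reads for the lysate. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

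By share of reads, the enriched fraction was mostly mRNA, whereas the lysate was mostly ribosomal RNA. Units coding for protein took 80.2% ± 0.73 (SD, n = 2) of reads in the enriched fraction and 26.5% ± 0.23 (n = 2) in the lysate, a 3.03-fold difference. Ribosomal RNA took 13.9% ± 0.70 against 65.3% ± 0.041, 4.69-fold less in the enriched fraction. Transfer RNA took 0.529% ± 0.089 against 6.01% ± 0.26, which is 11.4-fold less. Small RNAs made up 0.689% ± 0.0081 of enriched and 0.374% ± 0.011 of lysate reads. For every class except antisense RNA the gap between groups exceeded the spread within each group many times over. Even so, 2 against 2 libraries cannot give an exact two-sided permutation p under 0.333, the value reached by each class. As shares of summed RPKM, in which short RNAs weigh more, mRNA took 61.3% ± 1.9 against 8.95% ± 0.26 and tRNA 11.8% ± 1.6 against 56.6% ± 1.1. On that measure rRNA took 15.7% ± 0.52 against 31.1% ± 0.85, and small RNAs 10.5% ± 0.21 against 2.38% ± 0.018.

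**Figure D1:**
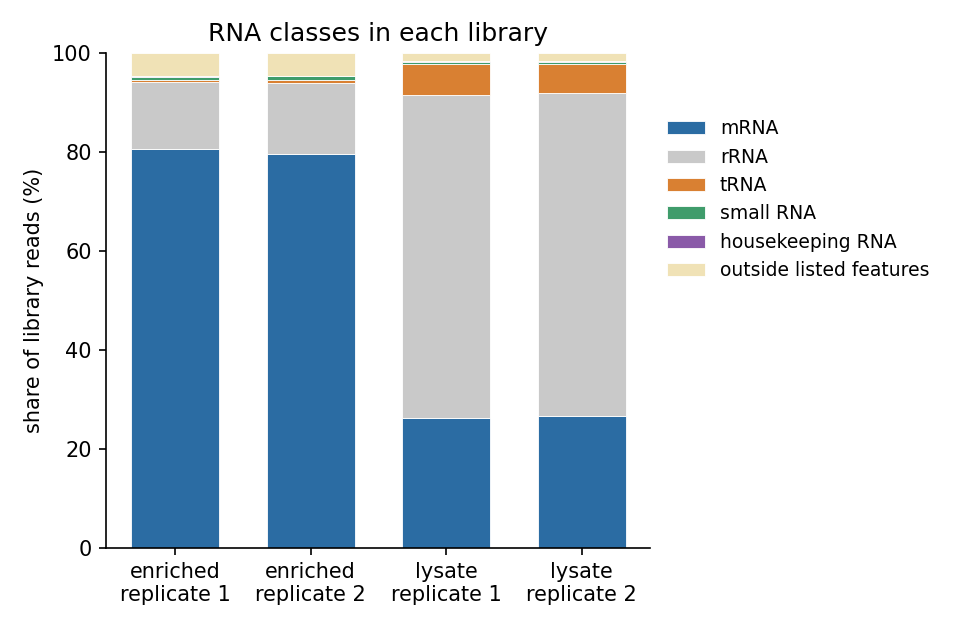
Share of library reads (%, y axis) taken by each RNA class in the 4 libraries (stacked bars, 1 per library, with reads outside listed features on top; antisense RNA is too small to draw). The blue mRNA segment spans about 80% of both enriched libraries and about 26% of both lysates, and the grey rRNA segment shows the opposite.

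The stable RNAs of translation were lower in the enriched fraction without exception. All 43 tRNAs fell, by 3.42-fold to 17.1-fold with a median of 11.5-fold. The lowest was tRNA-Gln(TTG), with 1435 ± 253 RPKM in the enriched fraction and 24503 ± 1898 in the lysate (n = 2 each; log2 difference −4.10, SE 0.14, limma adjusted p = 4.35e-07). It was followed by tRNA-Ser(CGA) at −4.08, tRNA-Glu(TTC) at −4.04 and tRNA-Arg(ACG) at −3.99. The rRNAs fell as well, 16S by 4.18-fold, 23S by 5.08-fold and 5S by 5.22-fold. Each of the 3 housekeeping RNAs fell: the transfer-messenger RNA ssrA, which rescues stalled ribosomes, by 6.90-fold, the RNase P RNA CCNA_R0061 by 5.20-fold and the signal recognition particle RNA CCNA_R0005 by 3.85-fold.

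Small RNAs were mostly higher in the enriched fraction, though less so than mRNA. Of 94 tested, 88 rose, 4 fell and 2 did not pass the test, and the median log2 difference was 1.07 against 1.57 for mRNA units; 87 of the 94 lay below the mRNA median. Among those that rose, CCNA_R0103 (chromosome positions 339708 to 339810) went from 70.5 ± 8.1 to 260 ± 8.0 RPKM, a log2 difference of 1.87 (SE 0.075, limma adjusted p = 8.84e-07). CCNA_R0127 (1.79), CCNA_R0180 (1.77) and CCNA_R0154 (1.72) came next. The 4 that fell were CCNA_R0186 (3.55-fold), CCNA_R0077 (2.40-fold), CCNA_R0144 (1.31-fold) and gsrN (1.19-fold), a small RNA of the general stress response; they are named here because they are few. The carbon starvation RNA crfA rose 1.59-fold. Whether counting used the strand is not given in the sources used here, so antisense values may include reads of the opposite strand. Of the 3 antisense RNAs tested, CCNA_R0006 rose 2.59-fold, CCNA_R0070 fell by 1.48-fold and CCNA_R0042 did not pass (log2 0.18, adjusted p = 0.056). Set against the remaining features with camera at a preset correlation, small RNAs ranked lower (adjusted p = 0.00013), as did antisense RNAs (6.19e-05). With an estimated correlation the tRNA call held (adjusted p = 0.0489), and the others did not: adjusted p = 0.068 for rRNA, 0.098 for small RNA, 0.068 for antisense RNA and 0.058 for housekeeping RNA.

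**Figure D2:**
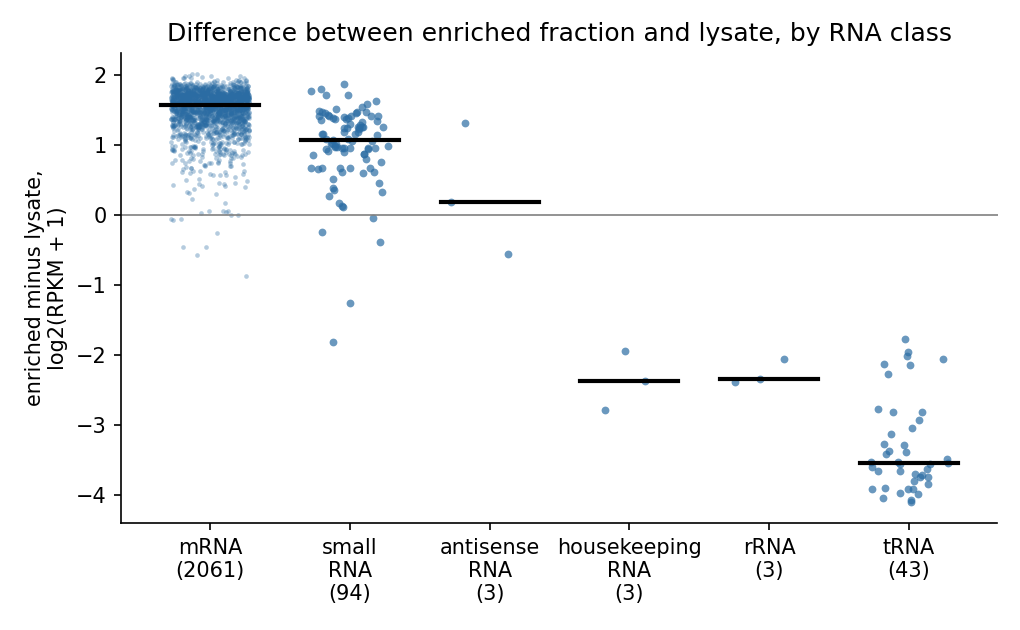
Enriched minus lysate difference in log2(RPKM + 1) (y axis) for each tested feature (points, spread sideways at random) by RNA class, with the number of features in parentheses and the class median as a black line. Medians are 1.57 for mRNA, 1.07 for small RNA, −2.35 for rRNA and −3.55 for tRNA.

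Nearly every mRNA was more abundant, relative to library size, in the enriched fraction. Of 2061 mRNA units tested, 2045 rose, 4 fell and 12 did not pass the test, with a median fold of 3.13. On log2(RPKM + 1), the largest rise among units with a gene symbol was in the nuo operon of respiratory complex I (positions 2158098 to 2177472). It went from 277 ± 1.3 to 1047 ± 27 RPKM, a log2 difference of 1.92 (SE 0.031, limma adjusted p = 4.12e-08). By the ratio of mean RPKM, the low unit sgt2 rose slightly more (3.81-fold against 3.78-fold). Close behind were the cytochrome oxidase operon that starts with ctaG (1.90), the stalk protein gene stpX (1.90), the mismatch repair gene mutL (1.90), hdaA (1.89), whose product restrains DnaA, the flagellar regulator fliX (1.89), the ribonucleotide reductase gene nrdJ (1.89) and recF with gyrB (1.88). Among units without a symbol, CCNA_03533 and CCNA_01438 rose most on log2(RPKM + 1) (both 2.01). Of units with a symbol only the flagellin gene fljL fell, from 155 ± 6.2 to 113 ± 7.1 RPKM (log2 −0.46, SE 0.051, adjusted p = 0.00016). Without a symbol, CCNA_00977 (−0.87) and CCNA_03762 (−0.57) fell furthest. The CCNA_00977 unit, at positions 1057167 to 1058162, overlaps a tRNA gene, with strand not considered. The remaining unit that fell, CCNA_03353 (−0.46), named here because so few did, contains the small RNA CCNA_R0077 and lay at 0.05 relative to the mRNA median once the reads of that RNA were subtracted.

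These directions depend on what the libraries are scaled to, because RPKM in the lysate is diluted by rRNA and tRNA. Over all classes, limma called 2134 features higher and 58 lower on RPKM. With each library centred on its median mRNA unit and the pseudocount of 1, the split was 575 higher and 656 lower. On that scale centring gave 35.0% false calls in data simulated with fewer and balanced changes, a share that need not hold here. With rRNA and tRNA left out before rescaling the split was 709 and 419. Centring each library on its median mRNA level, without a pseudocount, lowers the log2 differences by 1.61, and mRNAs are described below relative to that level, called the mRNA median.

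Relative to the median mRNA, most transcripts entered the pellet to a similar degree. Of the 2061 units, 93.5% lay within 0.5 log2 units of the median; limma called 567 above it, 414 below it and 1080 on neither side. The middle unit itself lay at 0.036, and centred on the median difference of the units, a choice made after the data were examined, the split turned to 395 above and 475 below. Departures were one-sided: no called unit lay more than 0.5 above, the highest reaching 1.39-fold, whereas 134 lay more than 0.5 below and 37 more than 1 below. The replicate SD was 0.062 log2 units in the enriched fraction and 0.086 in the lysate. Units above the median with a symbol were led by sgt2 (0.32, SE 0.11), the nuo operon (0.31, SE 0.032), fliX (0.31) and stpX (0.30). Behind them lay hvyA (0.30), mutL (0.30), nrdJ (0.29) and ctaG (0.29). The place of sgt2 rests on a low lysate level, 3.21 ± 0.30 RPKM (limma adjusted p = 0.036). Without enriched replicate 1 the counts were 235 above and 270 below, and without enriched replicate 2 they were 258 and 263.

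The 8 units with symbols that lay furthest below the median did so by about 1 log2 unit or more. The flagellin genes fljL (−2.07, SE 0.046) and fljM (−1.67, SE 0.079) were lowest. The units of the cold shock genes cspB (−1.62, SE 0.050) and cspA with CCNA_02996 (−1.56, SE 0.035) followed. The pilin gene pilA lay at −1.06 (SE 0.055), aimB at −1.04 (SE 0.031) and the thioredoxin gene trx1 at −0.99 (SE 0.048), each with a limma adjusted p of at most 9.28e-08. On RPKM, fljM (log2 −0.06, adjusted p = 0.52), cspB (−0.01, adjusted p = 0.83) and cspA (0.05, adjusted p = 0.19) did not differ between fraction and lysate beyond the spread. The dnaX unit lay at −1.04, but it contains the signal recognition particle RNA CCNA_R0005, and after that RNA's reads were subtracted it lay at 0.17. Flagellin genes are close paralogs, and how reads shared between them were assigned is not given in the sources used here.

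Genes of the RNA decay machinery itself were split. The genotype of the strain, including at rne, is not given in the sources used here. Values are those of whole transcription units. The unit of the RNase E gene rne, with CCNA_03959, rose from 60.7 ± 0.0072 to 125 ± 4.1 RPKM. That of pnp, for polynucleotide phosphorylase, with CCNA_00034, CCNA_00035 and CCNA_00036, rose from 608 ± 7.2 to 1114 ± 11 RPKM. Relative to the mRNA median they lay at −0.57 (SE 0.037) and −0.74 (SE 0.031). The helicase gene rhlB (−0.07, limma adjusted p = 0.12) was not separated from the median. The aconitase gene acnA (−0.11, adjusted p = 0.020) lay slightly below it and hfq with CCNA_01820 (0.11, adjusted p = 0.025) slightly above. Calls this near may depend on the centring, since the middle unit itself lay at 0.036. The genes rhlE and rnd were not matched by symbol. Of the 5 units of this list, 3 lay below the median and 1 above (adjusted over the list alone, likewise 3 and 1).

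No gene list stood apart from the other features under the test fixed in advance. Of 5 ribosomal protein units, 4 lay below the mRNA median and none above, with rpsU at −0.82 (SE 0.035) and rplS with trmD at −0.42 (SE 0.035), while the large operon from CCNA_01304 to secY lay at −0.09. Of 7 respiratory units 4 lay above and none below, among them the cydAB unit (0.21, SE 0.055). All 7 are among the 515 longest mRNA units (2301 to 19374 nt), of which 193 lay above and 35 below. The list tests took no account of length. Whether the respiratory units differ from other units of similar length was therefore not tested. Of 7 units with RNA polymerase or sigma factor genes, 3 lay below and none above. Set against all other features, camera passed 0 of 12 lists after adjustment (smallest adjusted p = 0.346) and 0 at an unadjusted p under 0.05. Among mRNA units alone, camera passed 0 after adjustment (smallest adjusted p = 0.0928) and 3 before it, namely ribosomal proteins and the degradosome list downward and the respiratory chain upward. With an estimated correlation that smallest adjusted p was 0.927. The self-contained test fry, which asks only whether a list departs from the median, called these 3 lists and RNA polymerase at adjusted p of 0.0271, 0.0473, 0.0478 and 0.0478. Centred on the median difference, fry no longer called the respiratory chain (adjusted p = 0.0656).

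Motility and cell cycle units went both ways around the mRNA median. Of 28 flagellum and chemotaxis units, 7 lay above and 7 below (adjusted over the list alone, 8 and 7); the other flagellin units lay at −0.93 (fljN), −0.75 (fljK), −0.26 (fljJ) and −0.30 (fljO, adjusted p = 0.178), and flbT with flaF at −0.42, while the operon of fliP and fliO lay at 0.24. Of 31 cell cycle and polarity units, 13 lay above and 8 below (adjusted over the list alone, 13 and 9). The master regulator gene ctrA (−0.91, SE 0.041) and cpdR (−0.66, SE 0.052), which directs its degradation, lay lowest there, while divJ (0.24) and ftsA with ftsQ (0.22) lay above. Of 20 pili, stalk and holdfast units, 4 lay above and 6 below, including staR at −0.40. The abundant S-layer gene rsaA lay at −0.65 (SE 0.038), although its secretion gene rsaD lay at 0.11; its list of 17 envelope units had 7 above and 3 below. In the remaining tested lists the counts above and below were 8 and 2 of 25 for amino acid biosynthesis (matched by symbol, so that it includes aminoacyl-tRNA synthetase genes, among them both units below, lysS at −0.19 and glyQ with glyS at −0.12), 3 and 2 of 9 for chaperones and proteases, 3 and 0 of 5 for xylose and vanillate use, and 2 and 1 of 8 for toxin-antitoxin units. Median and mean relative log2 differed in sign for flagellum and chemotaxis (0.0038 and −0.18), cell cycle and polarity (0.04 and −0.04), envelope (0.06 and −0.0098) and toxin-antitoxin units (0.0044 and −0.0085).

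Longer transcription units were more enriched than shorter ones. Across mRNA units, which are not independent replicates, the log2 difference correlated with unit length at a Spearman rho of 0.35, and with no pseudocount rho was 0.30, 0.34 and 0.35 in the tertiles of lysate level. Among the 516 shortest units (47 to 769 nt) 222 lay below the mRNA median and 57 above, with a median of −0.13; among the 515 longest (2301 to 19374 nt) 35 lay below and 193 above, with a median of 0.09. Among the 516 units of 1356 to 2294 nt, 50 lay below and 186 above. Their median of 0.0885 was close to the 0.0889 of the longest, so the rise with length levelled off. The correlation with lysate level was 0.39, and 0.091 without the pseudocount.

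**Figure D3:**
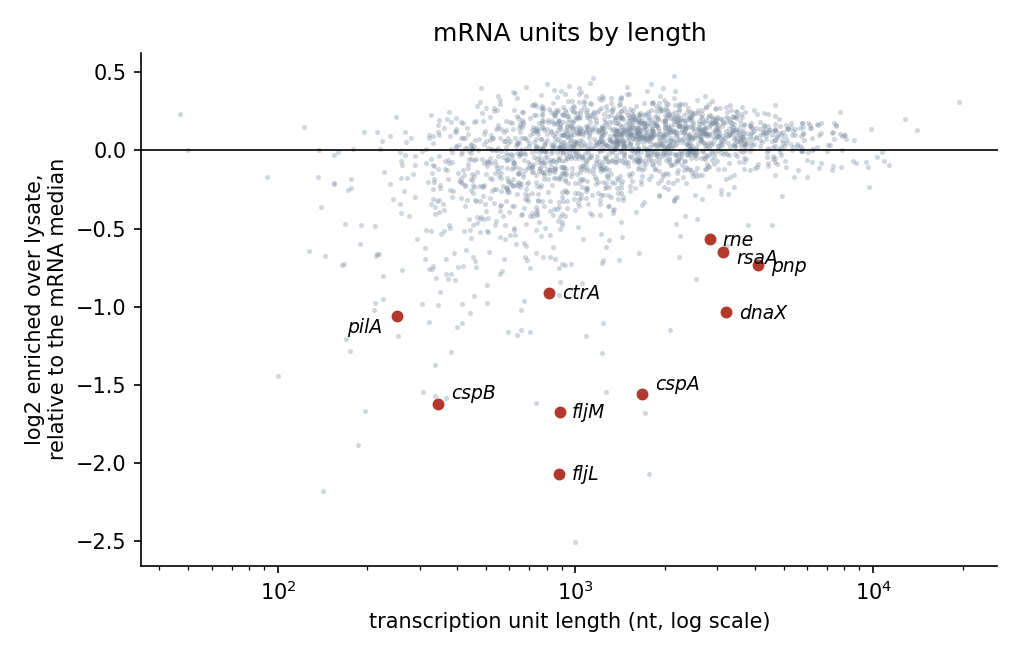
Log2 ratio of enriched fraction to lysate relative to the mRNA median (y axis) against transcription unit length in nt (x axis, log scale) for 2061 mRNA units (grey points), with some of the units named in the text in red. The scatter reaches far below the median and, at most, 0.47 above it; fljL lies at −2.07.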

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

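All tests in this part were chosen after the results were seen, and no biological explanation was tested, since the design holds a single contrast.

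Features outside the tested set also carried signal in the enriched fraction. In all, 88 features (75 mRNA units and 13 small RNAs) were listed in both enriched libraries and blank in both lysates, and 0 showed the reverse. A candidate explanation is the limit of 50 reads together with the smaller mRNA share of the lysate. If each of these features had differed by the median of its RNA class, 80 of the 88 would have had at most 50 reads in both lysates, with the highest expectation at 71.4 reads. What holds for the remaining ones stays open, because a blank gives only a bound. Against that bound the features were higher by at least 1.69-fold in the median. In a separate count, 80 of the 88 had both enriched values above the bound of both lysates.

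Reads outside every listed feature took 4.67% ± 0.067 of the enriched libraries and 1.64% ± 0.0029 of the lysates (n = 2 each), a ratio of 2.85. Blank features can hold at most 0.0316% of a library's reads.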

How the results depend on the processing

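Alternatives on blanks, voom weights, nested RNA reads, estimated correlations for classes, list tests among mRNA units and the fit relative to the mRNA median without a pseudocount were chosen after the data were examined; centring with the pseudocount of 1 was planned. Scaling moved the counts of higher and lower features most. Centred on the mRNA median the counts were 575 higher and 656 lower, and without rRNA and tRNA 709 and 419, by construction, since the dilution by stable RNA is removed. Under these scalings, in that order, the sign turned for rne (−0.53, −0.53), pnp (−0.69, −0.70), rhlB (−0.029, −0.031), acnA (−0.062, −0.073), cspA (−1.51, −1.51), pilA (−1.02, −1.02), aimB (−0.996, −1.003), dnaX (−0.990, −1.0001) and trx1 (−0.94, −0.94), among genes named by rule; the first of these lowers every difference by 1.56 and so turns any other rise smaller than that. The other alternatives run for these counts kept both within 1.5 times; scaling to summed mRNA reads was run only relative to the mRNA median.

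With 1 library left out, the lone library was assumed to vary like the other group. Counts then ran from 2129 to 2136 higher and 57 to 59 lower, and relative to the mRNA median from 235 to 671 above and 263 to 471 below; the low ends came without enriched replicate 1 (235, 270) or 2 (258, 263), and the cause was not tested. The direction held in every case for all 567 and 414 units, the call for 198 and 239. These units were chosen with all libraries included, so the kept direction was largely set in advance. The replicate number as a block gave 2135 higher and 57 lower and changed no class or list call. Same-numbered libraries did not deviate together (correlation −0.085), and the labels do not pair them. The medians of rRNA (−3.92), small RNA (−0.50), antisense RNA (−1.39) and housekeeping RNA (−3.94) minus mRNA were no longer past the threshold with an estimated correlation. For lists, fry passed 12 on RPKM, where all rise, turning flagellum and chemotaxis upward (adjusted p = 0.000241), and 4 relative to the mRNA median, turning ribosomal proteins (0.0271), degradosome (0.0473) and RNA polymerase (0.0478) downward; centred on the median difference it passed 3, those same lists at 0.0225, 0.0251 and 0.0251. It compares a list with no change, not with other genes. The correlation with lysate level (0.39) was 0.23 at 10 RPKM or more, 0.37 and 0.36 in replicates 1 and 2 alone, 0.40 without nested RNAs and 0.091 without a pseudocount. Features of 50 or fewer reads cannot be compared.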

Other observations

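The tests of explanations below were all chosen after the patterns were seen.

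The listed folds of the tRNAs were not alike, and how reads shared between tRNA copies were assigned is not given in the sources used here. Across the 43 tRNAs the log2 difference correlated with lysate level at a Spearman rho of −0.64, so that tRNAs with more reads fell further. The permutation p was 2e-05, the smallest that 100000 resamples can give, but tRNAs are not independent replicates. The lysate level also enters both values, with a minus sign in the difference. That alone can give a negative rho, and the permutation does not allow for it. Of the 43, 28 fell by more than 10-fold and 7 by less than 5-fold: tRNA-Ala(TGC) by 3.42-fold, a tRNA-Met(CAT) by 3.84-fold, tRNA-Leu(TAG) by 4.01-fold, tRNA-Leu(TAA) by 4.03-fold, tRNA-Val(TAC) by 4.15-fold, tRNA-Gly(TCC) by 4.37-fold and tRNA-Tyr(GTA) by 4.85-fold. Without enriched replicate 2, 5 fell by less than 5-fold and 32 by more than 10-fold, and tRNA-Leu(TAA) then fell by 7.12-fold; without enriched replicate 1 these counts were 9 and 22. Here rho lay between −0.71 and −0.53 when any single library was left out. The enriched libraries also differed from each other in this class, with 42 of 43 tRNAs higher in replicate 2, by 1.30-fold in the median. In the lysates 5 of 43 were higher in replicate 2.

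The 37 mRNA units more than 1 log2 unit below the mRNA median all stayed below it when any single library was left out. They were chosen with all libraries included, so this was largely set in advance. Listed small RNAs on the same strand overlap 6 of the 37, against 26 of the other 2024 units (Fisher's exact p = 1.42e-05). That leaves 31 that overlap none on their strand. Of the 6, CCNA_03965 lies inside CCNA_R0051 and 2 keep too few reads to tell; for the 3 that contain a small RNA and keep over 50 reads without it, dnaX, CCNA_03353 and CCNA_01916, the median moved to 0.088, so their low position may reflect the reads of that RNA. A tRNA or rRNA gene on either strand overlaps 3 of the 37, against 10 of the others (Fisher's exact p = 0.0013). That leaves 34 that overlap none. Other units within 10% of their length had a median of −0.12 against −1.29 for the 37. Since the 37 were chosen for low values and left out of the others, part of that gap was set in advance. The 37 had a median length of 442 nt, against 1356 nt for all units. A part for length therefore stays open, as do small RNAs that are not listed or lie on the opposite strand. Whether counting used the strand is not given in the sources used here.

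The median small RNA differed from the median mRNA unit by −0.49 log2 units without a pseudocount, and short length may account for part of this. From 100 to under 400 nt, 41 small RNAs lay at −0.20 relative to 148 mRNA units of that length (permutation p = 0.105), where −0.49 separated them from all mRNA. From 400 to under 800 nt the gap to 396 units was −0.27 (13 small RNAs, permutation p = 0.00968). Small RNAs are not independent replicates and lysate level was not matched. This p therefore does not settle whether length alone is enough there. Below 100 nt the gap was −0.55, but with only 3 mRNA units in that range, length and RNA class cannot be told apart for those 39 small RNAs.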
